A study of Homo sapiens with 8 samples.

How the data were processed

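Binding of the transcription factor GATA2 to chromatin was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in VCaP, an established human prostate cancer cell line that is castrate-resistant. Per the labels' protocols, the cells were kept without steroids for 72 h and received vehicle or 1 µM JQ1 for the last 24 h before harvest. The control samples carry a label of no treatment and are called untreated here. JQ1 is a small molecule that blocks the bromodomains of BET proteins, which read acetylated histones. Chromatin was fixed with formaldehyde, sonicated and precipitated with a GATA2 antibody, and the libraries were sequenced from single ends. The labels name 8 samples, of which 4 are GATA2 precipitates and 4 are input chromatin, with 2 replicates for each kind and treatment. The 4 precipitates each have a peak list, and no separate list was used here for the 4 inputs.

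Per the submitters' processing notes, Bowtie2, Picard and MACS2 were used with the genome build hg38, and their versions are not given in the sources used here. Per the labels, each peak list belongs to a single precipitate, so peaks had been called per sample and not on pooled samples. Each deposited line gives an interval, a summit, a score, a fold enrichment and the −log10 of a p-value and of a q-value, all as written by the authors' peak caller. The score in the deposited lists is the caller's whole-number score and was not used for any test. The fold enrichment in the deposited lists is a linear ratio at the summit. Tested on the values, it could be written as the precipitate's pileup over the local background, each with a pseudocount of 1, with the deposited −log10 p-value being the Poisson tail of the same pair. The −log10 q-values are the authors' adjusted values. The weakest q-value in each of the 4 lists lies just under 0.05. These peak values belong to the authors' calling of each list. They were used here to describe, rank or filter peaks within a list, after which the numbers of peaks were compared, and to estimate depth as described below.

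Peaks on chromosomes 1 to 22, X and Y were analysed. This left out 10 mitochondrial lines of the list of JQ1 replicate 1 and 8 lines on unplaced contigs in the list of untreated replicate 2. Each line counted as 1 peak. Peaks of the 4 lists that overlapped by at least 1 bp were merged into regions, and a region was recorded as present in a list when that list had a peak in it. A region present in both lists of a group was called recurrent. A region present in both lists of a group and in neither list of the other group was called separated. Shares carry 95% Wilson intervals, which cover counting error only. Chance overlap came from 100 random placements of the peaks on their own chromosomes. Peak numbers were compared on the log2 scale by a two-sided exact permutation test over the splits of the 4 lists into pairs of 2. With 2 lists against 2, the smallest p this test can give is 0.333, so that p 0.05 cannot be reached. The labels do not say whether replicates came from separate cultures, so that this p measures only the spread between these samples. Regions and genes are not replicates, and tests over them describe these libraries.

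Genes were taken from a RefSeq table of assembly GRCh38.p14, the same build as hg38. It gives the start and end of each of 20037 protein-coding genes on these chromosomes but no strand, exons or sequence. Several planned steps changed for that reason. Distances to a gene were measured to its span and not to its transcription start, with the shorter gene taken where spans tied. The promoter share became the share of summits within 1 kb of either end of a gene span. The share of peaks with a GATA motif was not analysed here. Of the 363 entries of 14 gene lists fixed before the data were examined, 362 were matched, and the lists are named with their results. For each list, the genes with a region present in all 4 peak lists within 50 kb of the span were counted. The count was set against 10000 random lists of equal size, matched on decile of gene density within 1 Mb and, since spans were used, on 5 classes of gene length. The two-sided p from the random lists was adjusted over the 14 lists by the Benjamini-Hochberg method. Between treatments, genes with an untreated recurrent region were compared by Fisher's exact test, two-sided, on whether they kept a recurrent region with JQ1. List members were set against all other such genes, with the same adjustment. Any JQ1 recurrent region within 50 kb of the span counted, also one at another place than the untreated region.

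The named genes follow a rule fixed before the data were examined. It takes 28 panel genes and the nearest gene of the 10 regions in all 4 lists with the best mean rank. It also takes the nearest gene of the 10 untreated-separated and of the 10 JQ1-separated regions whose poorer rank percentile was best, and at most 4 members per gene list, first by the number of lists with a peak and then by alphabet. Some of the genes that the rule takes are not reported here. Where other members are named, they were chosen after their values were seen.

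The lists carry no read totals. Under the relation above, the deposited fold and p-value of a peak together fix its whole-number summit pileup and its local background. Both were recovered for 100% of the peaks in each list to within 0.001 in −log10 p. The lowest background level, with the width of the narrowest peak taken as the fragment length, then gave an estimate of the effective depth used in calling. It was 7.87 reads per kb in untreated replicate 1, 8.83 in untreated replicate 2, 6.997 in JQ1 replicate 1 and 10.63 in JQ1 replicate 2. The pileups of untreated replicate 2 came out as whole numbers only after division by 0.686, as if its 12.9 reads per kb had been scaled down to its input. In the other lists the values fitted an input scaled down to the precipitate. A list called at greater effective depth reaches weaker sites, so that list lengths depend on depth as well as on binding. For an alternative chosen after seeing the data, recovered pileups and backgrounds were thinned to 5.60 reads per kb in 20 random draws and tested again at a common −log10 p of 4.51, 8, 16 or 32. On simulated lists without a true difference, the log2 ratio of replicate 2 was 0.14 as called and 0.02 after thinning at the common p minimum. Also tested on simulated data, the recovery returned the true pileup for 100% of 3535 peaks without scaling and 98.9% of 3848 scaled peaks. The search for separated regions returned 100% of 200 planted regions in each direction. These were planted among the strongest of their own group and left out of the other, which fixed that result. It checks the merging of the lists only, and not weak or falsely separated regions.

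The other alternatives were a q-value of 1e-05 or less, lists cut to the 4974 best peaks, all contigs, merged lines, summits within 100 bp, reciprocal overlap of 50%, the replicate number as a block, each replicate left out, and other gene windows. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.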

Results

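GATA2 ChIP-seq in VCaP cells was used to ask how the BET bromodomain inhibitor JQ1 affects the sites bound by GATA2, a zinc-finger transcription factor expressed in prostate cells. Peak lists of 2 untreated and 2 JQ1-treated precipitates were compared. Untreated replicate 1 held 6902 peaks, untreated replicate 2 held 27373, JQ1 replicate 1 held 4974 and JQ1 replicate 2 held 32404. The median peak was 216, 236, 212 and 224 bp wide in the same order, and the peaks covered 1598, 6976, 1132 and 7801 kb of the genome. The authors' median fold enrichment was 6.14, 7.46, 5.94 and 6.62 in these lists. The effective sequencing depth recovered from the lists ran from 6.997 to 10.63 reads per kb.

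The strongest GATA2 peaks of untreated cells were mostly found with JQ1 in the same replicate. Of the strongest 20% of peak intervals by p-value, 99.96% of untreated replicate 2 were overlapped in JQ1 replicate 2, and 88.5% of untreated replicate 1 in JQ1 replicate 1. Across replicates, where a long list met a short one, 58.0% of those of untreated replicate 2 were overlapped in JQ1 replicate 1 and 71.9% in untreated replicate 1. Of those of JQ1 replicate 2, 59.4% were overlapped in untreated replicate 1 and 53.9% in JQ1 replicate 1. Merging the 4 lists gave 36122 regions, of which 3236 were present in every list. The best-ranked of these lay on chromosome 15 at 101850029 to 101850413 (hg38), 30.0 kb from OR4F15, an olfactory receptor gene. Next came a region at 106993213 to 106993620 on chromosome 9 inside ZNF462, which codes for a zinc-finger protein, and a region at 171740720 to 171742159 on chromosome 3 inside PLD1, the gene of phospholipase D. The first 10 also included regions inside TOP6BL, the Notch coactivator gene MAML2, GRHL2, NDUFAF6 and the replication helicase gene CDC45, a region 9.79 kb from C1orf202, and a region 139 kb from the homeobox gene IRX3. In each of the 4 lists, all 10 stood within the top 0.503% of peaks by q-value. GRHL2 codes for an epithelial transcription factor, and its region at 101578922 to 101579699 on chromosome 8 had a −log10 q of 95.5 and 224.8 in the untreated lists and of 80.7 and 248.8 in the JQ1 lists.

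Nearly every region bound in both untreated replicates was found again with JQ1. Of 6365 untreated recurrent regions, 96.5% (95% Wilson interval 96.0 to 96.9) were present in at least 1 JQ1 list and 50.8% (49.6 to 52.1) in both. In the other direction, 97.1% (96.6 to 97.6) of 4714 JQ1 recurrent regions were present in at least 1 untreated list and 68.7% (67.3 to 70.0) in both. Randomly placed JQ1 peaks overlapped 0.763% of the untreated recurrent regions on average and 1.11% at most. The share found again rested on the long list of replicate 2. Without replicate 2, 48.6% of the regions of untreated replicate 1 were in the JQ1 list, and without replicate 1 the share was 80.8%.

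**Figure D1:**
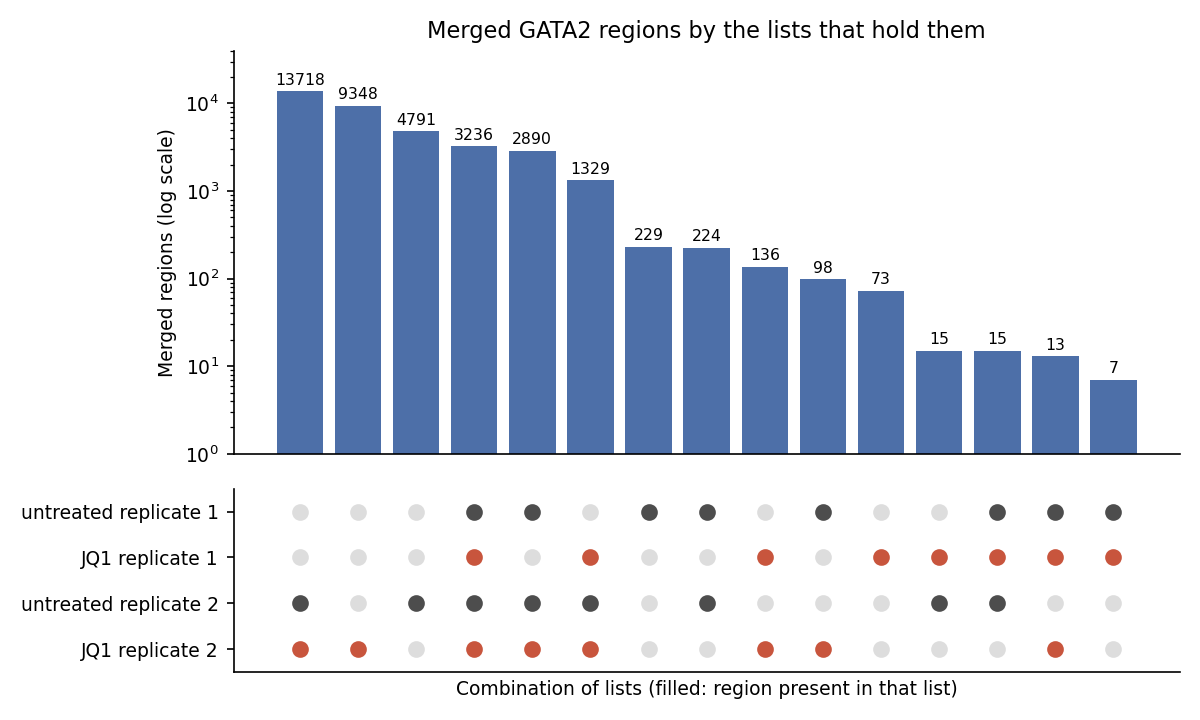
Number of merged GATA2 regions (log scale) for each combination of the 4 peak lists. Filled circles mark the lists that hold the region, in grey for untreated and in red for JQ1. The combination of both replicate 2 lists was the most frequent with 13718 regions, 3236 regions were in all 4 lists, and 224 and 136 regions followed the treatment.

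The number of GATA2 peaks did not differ between treatments beyond the spread between replicates. Untreated lists held 17138 ± 14475 peaks (SD, n = 2) and JQ1 lists 18689 ± 19396 (SD, n = 2). The ratio of geometric means was 0.92, or −0.11 on the log2 scale, with a p of 1 in the exact permutation test, whose smallest possible p was 0.333. The replicates went in opposite directions. The JQ1 list had 27.9% fewer peaks than the untreated list in replicate 1 and 18.4% more in replicate 2.

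Peaks of high fold enrichment were fewer in the JQ1 list of each replicate. Peaks with the authors' fold enrichment of 10 or more numbered 945 untreated and 486 with JQ1 in replicate 1, and 8827 untreated and 8174 with JQ1 in replicate 2. At a fold of 20 or more the numbers were 73 and 19 in replicate 1 and 2155 and 1661 in replicate 2. The exact permutation p was 0.667 at both limits, since replicates differed by more than treatments did. A fold limit also depends on depth, since the pseudocount of 1 weighs more at low background. Effective depth was lower with JQ1 in replicate 1 (6.997 against 7.87 reads per kb) and higher with JQ1 in replicate 2 (10.63 against 8.83). Peaks of low p-value gave another order in replicate 2 at each list's own depth, where JQ1 had 15457 peaks and untreated 14278 at a −log10 p of 16 or more. When all lists were thinned to the same effective depth, the ratio of replicate 2 turned from above 1 to below 1 at a −log10 p of 8 or more, with 18765 untreated peaks and 18195 with JQ1. At 16 or more, log2 JQ1 over untreated was −0.63 in replicate 1 and −0.25 in replicate 2. The fold limits and the thinning were chosen after seeing the data.

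**Figure D2:**
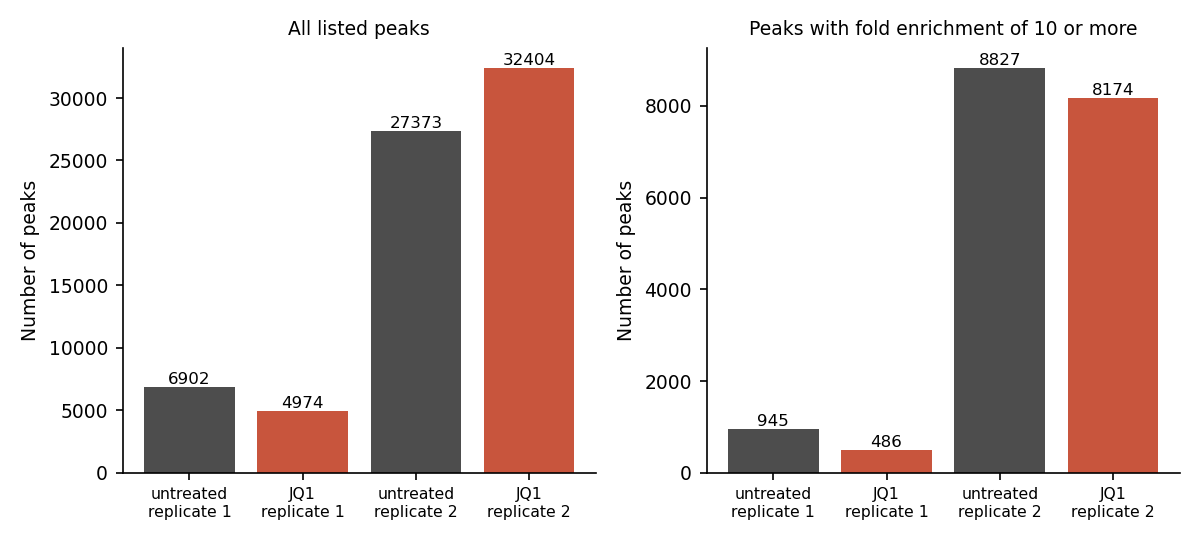
Number of GATA2 peaks in each list (left) and of those with the authors' fold enrichment of 10 or more (right), each bar being a single list. The JQ1 list was longer than the untreated list in replicate 2 for all peaks, with 32404 against 27373, and shorter among peaks of high fold, with 8174 against 8827.

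**Figure D3:**
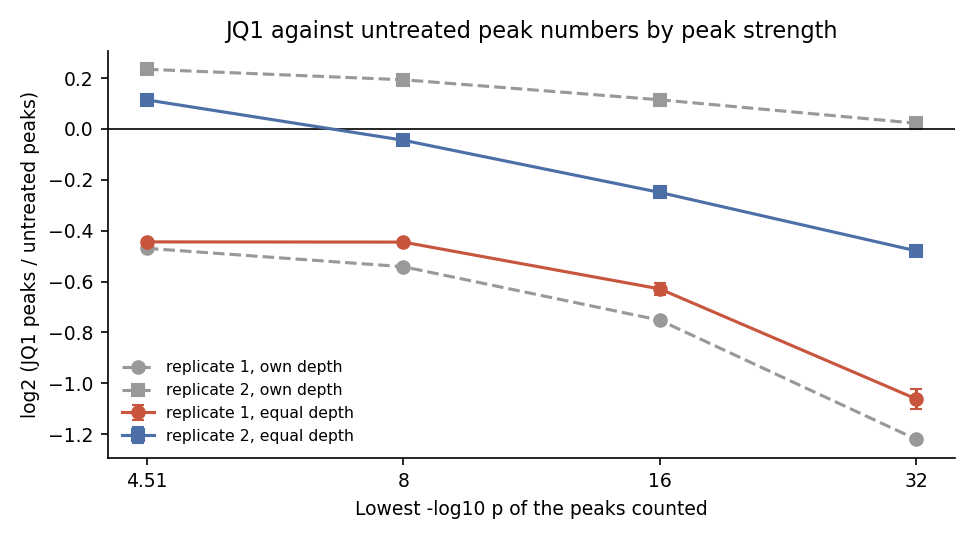
Log2 ratio of JQ1 to untreated peak numbers within each replicate against the lowest −log10 p of the peaks counted, at each list's own depth (grey, dashed) and after thinning to equal effective depth (colour). Error bars are the SD over 20 thinning draws and are mostly smaller than the symbols. At equal depth the ratio of replicate 2 went from 0.11 at 4.51 to −0.48 at 32.

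Some GATA2 regions were present in both untreated lists and absent from both JQ1 lists. There were 224 of these untreated-separated regions. The leading one lay inside MLLT3, which codes for a component of the transcription elongation machinery, at 20553621 to 20553864 on chromosome 9, with a −log10 q of 24.7 and 37.8 in the untreated lists. The others among the first 10 lay inside AKAP19, CHST8, FHIT and MIPOL1, and nearest to CLDN16, TNS3, NUF2, CPEB2 and LOC105370706. CLDN16 codes for a tight junction claudin and its region was 17.5 kb away. Those assigned to LOC105370706, CPEB2, TNS3 and NUF2 were 35.9, 124, 341 and 452 kb away. CHST8 is a sulfotransferase gene, TNS3 codes for a focal adhesion protein and NUF2 for a kinetochore protein.

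Conversely, 136 regions were JQ1-separated, that is, present in both JQ1 lists and in neither untreated list. The leading one was inside HS3ST5, a heparan sulfate sulfotransferase gene, at 114131947 to 114132455 on chromosome 6, with a −log10 q of 20.8 and 43.4 in the JQ1 lists. The next was inside the sialyltransferase gene ST6GALNAC3, at 76579667 to 76580039 on chromosome 1, with values of 13.2 and 65.7. The rest of the first 10 lay inside EPHA5, an ephrin receptor gene, STAP1, CHN1 and CTNND2, the gene of delta-catenin, and nearest to ASCL4, CCDC160, GRIN3A and BCAS1. GRIN3A, which codes for a glutamate receptor subunit, was 164 kb away. BCAS1, ASCL4 and CCDC160 were 156, 56.5 and 6.26 kb from their regions.

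Separated regions ranked lower than regions found in all 4 lists, an order that follows partly from requiring the latter in every list, short ones included. Their median peak stood at the top 66.3% and 58.6% of the untreated lists and at the top 75.8% and 50.5% of the JQ1 lists by q-value. Regions in all 4 lists had medians at the top 28.9% and 7.92% of the untreated lists and 36.9% and 7.41% of the JQ1 lists. The treatment pairing gave 360 separated regions, the crossed pairing (untreated replicate 1 with JQ1 replicate 2) gave 113, and the replicate pairing gave 13725. With lists of equal length, the treatment pairing gave 350 untreated-separated and 326 JQ1-separated regions, the crossed pairing 253 and the replicate pairing 939. With a reciprocal overlap of 50%, the treatment pairing gave 375 regions and the crossed pairing 197. At a q-value of 1e-05 or less, 88 regions were JQ1-separated. Without replicate 1 or without replicate 2, the counts of regions in only a single list per group ran from 3475 to 5046 for untreated and from 1573 to 9596 for JQ1.

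Peaks of the short replicate 1 lists lay within the long replicate 2 lists of either treatment, with a small preference for the same treatment. Peak intervals of untreated replicate 1 were overlapped for 94.8% (94.3 to 95.3) in untreated replicate 2 and for 92.9% (92.3 to 93.5) in JQ1 replicate 2. Those of JQ1 replicate 1 were overlapped for 95.2% (94.6 to 95.8) in untreated replicate 2 and for 97.7% (97.2 to 98.1) in JQ1 replicate 2. Among intervals found in only a single replicate 2 list, untreated replicate 1 had 243 in untreated and 113 in JQ1, and JQ1 replicate 1 had 32 and 153. The odds ratio was 10.3 (95% interval 6.61 to 15.99, counting error only). It was 2.70 with lists of equal length, 6.32 for summits within 100 bp and 1.58 with a reciprocal overlap of 50%.

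GATA2 regions present in all 4 lists lay near androgen-regulated genes and luminal prostate transcription factor genes more often than near matched random genes. Of 30 androgen-regulated genes, 15 had such a region within 50 kb, against 4.81 in random lists (permutation p = 0.0001, the smallest that 10000 random lists can give, adjusted p = 0.0014). They included ABCC4, which codes for a drug and prostaglandin transporter, C1orf116 and EAF2, an elongation factor partner. ACSL3, a fatty acid ligase gene, had a peak in each list but no region common to all 4. The 15 genes shared 19 distinct regions, since KLK2, KLK3 and KLK4 are neighbours. Of 27 transcription factor genes, 12 had a region, against 4.72 in random lists (permutation p = 0.0009, adjusted p = 0.0063). CREB3L1, EHF and ERG were among them. With lists of equal length, which hold fewer regions, 8 androgen-regulated genes had one against 3.22 in random lists and 8 transcription factor genes against 3.27 (permutation, adjusted p = 0.0889 for both). At a q-value of 1e-05 or less the numbers were 9 against 3.98 (permutation, adjusted p = 0.0987) and 11 against 3.96 (permutation, adjusted p = 0.0112).

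The other 12 groups were not distinguished from random lists, with adjusted p of 0.818 or more. Genes of androgen synthesis and metabolism had a region at 6 of 28, among them DHRS9, HSD17B6, HSD3B1 and SRD5A1, which code for steroid-converting enzymes. BET proteins and coactivators had one at 5 of 28, including BRD3, NCOA1, NCOA2 and NCOA3. Genes often lowered by BET inhibitors had one at 3 of 22, namely CDK6, E2F1 and E2F2, and genes often raised by them at 0 of 16. Cell cycle genes had 2 of 28, E2F1 and MKI67. Among cell type markers, the counts were 3 of 27 luminal epithelial genes (ACP3, AMACR and PROM1), 3 of 24 basal epithelial genes (CD44, LAMA3 and TP63) and 1 of 24 neuroendocrine genes (SOX2). They were 4 of 28 for blood and endothelial genes associated with GATA2 (CD34, HHEX, LYL1 and MS4A2), 2 of 26 for hepatocyte genes (CYP3A4 and CYP8B1) and 3 of 26 for stromal and immune genes (ACTA2, CNN1 and DES). Housekeeping genes had 2 of 28, SDHA and YWHAZ.

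**Figure D4:**
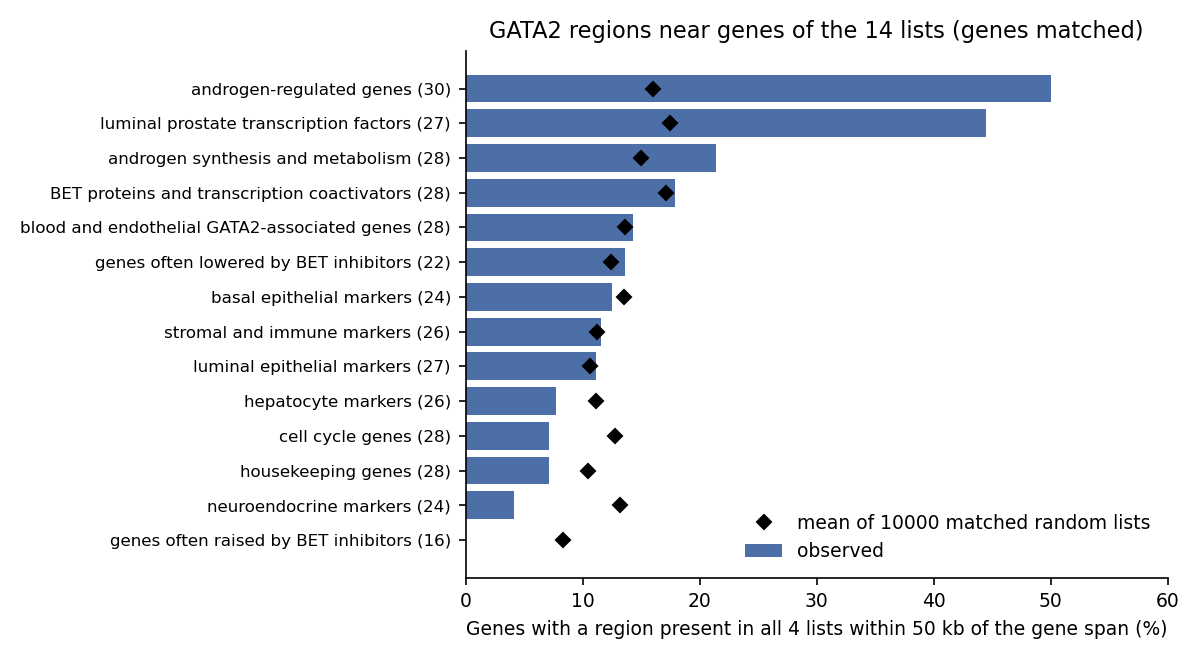
Share of the genes of each list (number of genes in brackets) with a GATA2 region present in all 4 peak lists within 50 kb of the gene span, in percent. Bars show the observed share and diamonds the mean of 10000 matched random lists. Androgen-regulated genes (15 of 30) and luminal prostate transcription factors (12 of 27) stood above their diamonds by more than any other list.

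None of the 14 gene lists passed the test for keeping or losing recurrent GATA2 regions with JQ1 more than other genes. Of 4869 genes with an untreated recurrent region within 50 kb, 2920 also had a JQ1 recurrent region. These were counted as keeping one even where the JQ1 region lay at another place, as at ACSL3. Among androgen-regulated genes 16 of 20 kept one, or 80% against 59.9% of other genes (Fisher's exact test, p = 0.0713, adjusted p = 0.499). Among transcription factors 12 of 17 kept one (exact p = 0.462, adjusted p = 0.748). Genes often raised by BET inhibitors kept 0 of 4, which were CLU, SAT1, SERPINI1 and TXNIP (exact p = 0.0256, adjusted p = 0.359). TXNIP, which codes for a thioredoxin inhibitor, was named after its values were seen. By Fisher's exact test 0 of the 14 lists passed an adjusted p of 0.05, and 1 had an unadjusted p under 0.05. A gene was counted as not keeping a region when the short list of JQ1 replicate 1 had no peak there, even if JQ1 replicate 2 had one.

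At the kallikrein locus, GATA2 occupied the same 3 regions in all 4 lists. KLK3, which codes for prostate-specific antigen (NCBI gene 354, chromosome 19, 50854915 to 50860764), and its neighbour KLK2 are androgen-regulated. The regions had summits at 50842272, 50850886 and 50869675, all outside both gene spans. The third was also the common region of KLK4. The region at 50842272 had a −log10 q of 99.5 and 173.6 in the untreated lists and of 43.2 and 171.3 in the JQ1 lists. It was the strongest of the locus in each list except untreated replicate 2, where the region at 50850886 had 203.5. At TMPRSS2, an androgen-regulated protease gene, 3 regions were likewise common to the 4 lists.

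At FOXA1, the gene of a pioneer factor, a single common region had its summit at 37547098 on chromosome 14, 42.4 kb from the span. Its −log10 q was 24.9 and 102.2 in the untreated lists and 11.5 and 52.0 in the JQ1 lists. A common region inside NCOA3, a nuclear receptor coactivator gene, had its summit at 47540706 on chromosome 20. The values there were 21.7 and 171.7 untreated and 26.9 and 153.2 with JQ1. No test was run on these values.

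**Figure D5:**
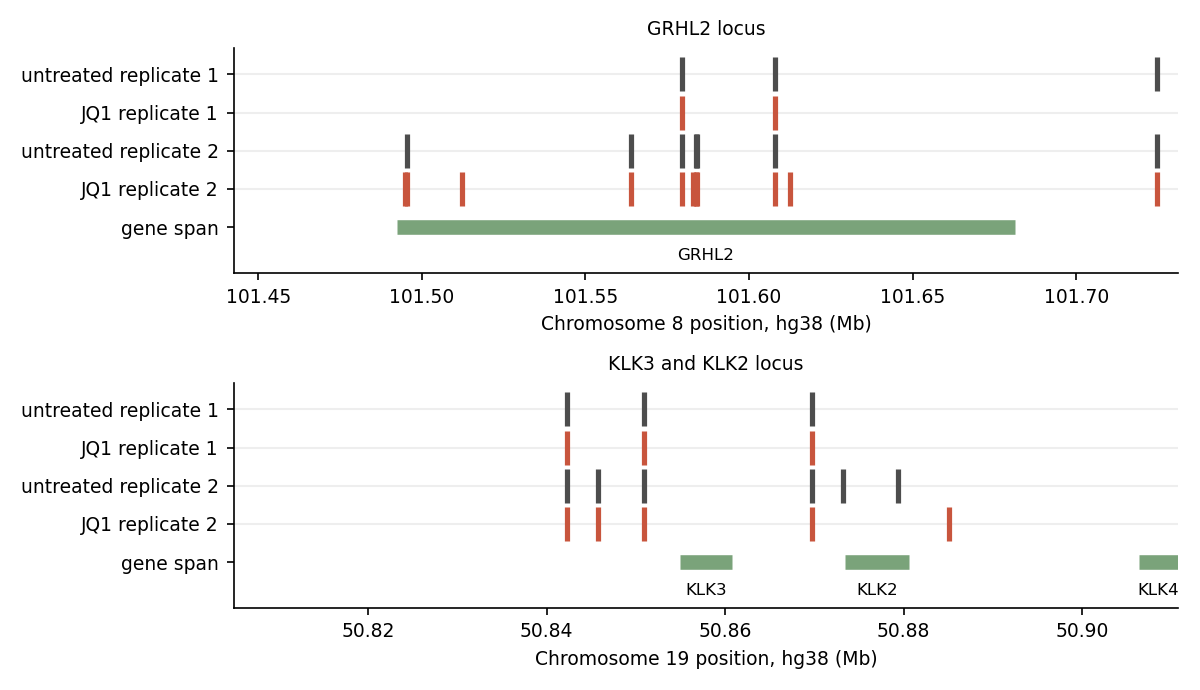
Positions of merged GATA2 regions (ticks at the summit of the strongest peak) in each list within 50 kb of GRHL2 on chromosome 8 and of KLK3 on chromosome 19, in Mb of hg38, with gene spans in green. The gene KLK4 runs beyond the right edge. GRHL2 had 2 regions in all 4 lists, both inside its span, and the KLK3 locus had 3.

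Over the 28 panel genes, 19 had an untreated recurrent region within 50 kb, 14 had a JQ1 recurrent region and 13 a region in all 4 lists. The genes with a region in all 4 lists included KLK3, KLK2, TMPRSS2, FOXA1, ERG, NCOA3, GRHL2, KLK4, STEAP4, PMEPA1, ELL2 and ABCC4. ACSL3 had an untreated and a JQ1 recurrent region at different places. GATA2 itself, HOXB13 and MYC were among the genes with an untreated recurrent region and no JQ1 recurrent one. Each of these 3 had a peak in JQ1 replicate 2 and none in JQ1 replicate 1, the shortest list. UGT2B17, UGT2B15, GATA3 and SLC45A3 had peaks in both replicate 2 lists only, FKBP5 in untreated replicate 2 only, and UBE2C and HEXIM1 in JQ1 replicate 2 only. The HEXIM1 peak had a −log10 q of 1.37, near the calling limit, against 6.37 for that of FKBP5 and 9.07 for that of UBE2C. CCND1 and TRPS1 had no peak in any list. Within 10 kb of the gene span, 10 genes had an untreated and 8 a JQ1 recurrent region.

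Few GATA2 peaks lay at gene ends with either treatment. Summits fell inside protein-coding gene spans for 49.7% ± 0.890 (SD, n = 2) of untreated and 49.99% ± 0.178 (SD, n = 2) of JQ1 peaks (exact permutation p = 1), against 42.7% of random positions. Summits within 1 kb of an end of a gene span made up 2.23% ± 0.254 (SD, n = 2) of untreated and 2.11% ± 0.0252 (SD, n = 2) of JQ1 peaks (exact permutation p = 1), against 2.30% of random positions. The difference of −0.11 percentage points was −0.36 within 3 kb, 0.09 with lists of equal length and 0.05 without replicate 1. Random positions were drawn evenly between the first and last peak of each chromosome. Sequence where no peak can be called was not left out, so the gap to random positions may lie partly in that.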

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

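The tests in this part were chosen after the results were seen, except for the equal-length lists and the reciprocal overlap, which were planned. The mitochondrial genome, which the comparisons did not use, had 10 peak lines in JQ1 replicate 1 and none in the other 3 lists, with fold enrichments of 1.36 to 1.87.

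Both lists of replicate 2 were several times longer than those of replicate 1, by 3.97 times without and 6.51 times with JQ1. Sequencing depth does not account for most of this gap, since the ratios were 3.88 and 5.71 after thinning to equal effective depth. A weaker pull-down of the same sites in replicate 1 stays open. It predicts short lists nested in long ones, and at least 94.8% of the replicate 1 intervals were in the replicate 2 list of their group. No biological explanation was tested, because the design gives none for a replicate.

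The JQ1 list was shorter in replicate 1 and longer in replicate 2, while peaks of high fold were fewer with JQ1 in both, as were peaks with a −log10 p of 16 or more after thinning to equal depth. Unequal effective depth is argued against as the whole cause in replicate 1. The log2 ratio there was −0.44 at equal depth and a −log10 p of 8 or more. For all peaks of replicate 2 unequal depth stays open. There 0.1140 was left at the common p minimum, against 0.0249 on simulated lists without a true difference. Thinning cannot restore sites under a list's own calling limit. The simulated lists share that limit, but their number of weak sites was assumed, so this test cannot decide. For peaks of replicate 2 with a −log10 p of 8 or more, unequal depth remains a candidate explanation, as their ratio at equal depth was −0.0445. At 16 or more the ratio nearer to 0 was −0.25, in replicate 2, which lower GATA2 binding at strong sites with JQ1 and a weaker pull-down in both JQ1 libraries predict alike. These cannot be told apart, because each treatment has only its own precipitates and no reference chromatin was added, as far as the labels say.

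The treatment pairing of the 4 lists separated more regions than the crossed pairing. Chance crossing of the calling threshold would give similar numbers, but in equal-length lists the treatment pairing had 676 regions and the crossed pairing 253, a ratio of 2.67, and with a reciprocal overlap of 50% they had 375 and 197. At equal effective depth the numbers were 439 and 123, a ratio of 3.57. Unequal depth stays open, since thinning cannot restore sites that a list had missed and was not simulated for separated regions. An effect of JQ1 on a small set of sites remains a hypothesis, and a library property that goes with the treatment stays open too. The 4 lists allow only 3 splits, too few for a share under 0.05, and the replicate pairing gave the highest count of all.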

How the results depend on the processing

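Of the alternatives below, the common p minimum, the fold limits, equal effective depth and the genes with windows that do not overlap were chosen after the data were seen. The change in peak number kept its sign in 11 of 12 alternatives, and no design of 2 against 2 lists could pass the threshold. Over all listed peaks the sign came from replicate 1, as replicate 2 went the other way. The fold and −log10 p limits counted stronger peaks only. The change was −1.16 at a fold of 20 or more, −0.54 at a fold of 10 or more and −0.47 without replicate 2. It reversed to 0.24 without replicate 1, because each replicate then stands alone. The replicate numbers share only a label, with 2 pairs and no stated source for a pairing. Peak names in both replicate 2 lists carry a 3, and those in the replicate 1 lists a 1 or no replicate number, so that the replicates may have been run as sets, which was not tested. With replicate as a block the change was −0.11 (SD 0.51, exact sign-flip p 1, smallest possible 0.5), with 224 and 136 separated regions. These values equal those of the main analysis by definition. The block is thus no separate check of them, although it counts among the 11 alternatives that kept the sign. Leaving out a replicate leaves 1 list per group. Retention then ran from 48.6% to 80.8% for untreated and from 67.6% to 68.8% for JQ1 regions, the regions counted from 6756 to 26221 and from 4854 to 30771, and separated regions from 3475 to 5046 and from 1573 to 9596. The difference in the share near gene ends ran from −0.27 to 0.0496 percentage points. With equal-length lists, retention was 88.9% for untreated and 89.0% for JQ1, recurrent regions numbered 3140 and 2958, separated regions 350 and 326, the odds ratio was 2.70, 0 gene lists passed for excess occupancy (2 in the main analysis), and the gene end difference turned to 0.0905. At a q-value of 1e-05 or less, JQ1 retention was 97.6%, 88 regions were JQ1-separated and 1 gene list passed. The other 3 settings for excess occupancy (10 kb, nearest gene only, windows that do not overlap) gave 2 lists each. The odds ratio was 6.32 for summits within 100 bp and 1.58 with reciprocal overlap of 50%, which gave an untreated retention of 96.0%. At equal effective depth untreated retention was 94.96%. Within 10 kb, panel genes with recurrent regions were 10 untreated and 8 with JQ1. The cause of these changes was not tested beyond the shorter lists and narrower windows that the settings make. The count of gene lists differing in retention was 0 in all 4 alternatives by Fisher's exact test, with the smallest adjusted p from 0.342 to 0.898. The GATA motif share and all its alternatives were not run, nor were distances to transcription starts. Weak sites were found again least often, for causes that were not separated: of the weakest 20% of untreated replicate 1 intervals 23.7% were in JQ1 replicate 1, and of the strongest 20% 88.5%.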

Other observations

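The genes and regions in this part were chosen after their values were seen. Regions common to the 4 lists were counted within 50 kb of each gene span, which gives long genes more sequence to hold them. DLG2, which codes for a synaptic scaffold protein, and FHIT, a gene at a common fragile site, each had 7. MACROD2, CTNNA3, FNDC3B, CHODL, HEMK2 and TOX had 6 each. MACROD2 spans 13995516 to 16053197 on chromosome 20 and had 19 untreated recurrent but 7 JQ1 recurrent regions, with 8 peaks in JQ1 replicate 1 and 48 in JQ1 replicate 2.

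A few genes had 2 untreated-separated regions nearby. DUSP6, which codes for a phosphatase of the ERK pathway, had them at 89326259 to 89326595 and 89390079 to 89390454 on chromosome 12, both outside its span, and kept a region common to all 4 lists between them. The first had a −log10 q of 2.66 and 2.01 in the untreated lists, near the calling limit, and the second 10.8 and 12.7. The unfolded protein response gene ERN1 had them at 64051316 to 64051490 and 64082226 to 64082426 on chromosome 17, inside its span, with 2.68 and 9.17 in the first and 7.01 and 8.82 in the second. In ERG, a region at 38570432 to 38570687 on chromosome 21 had a −log10 q of 40.7 in untreated replicate 1 and 23.5 in untreated replicate 2. It was missing from JQ1 replicate 1 and had 8.98 in JQ1 replicate 2. Another ERG region, at 38392672 to 38393124, went the other way, missing from untreated replicate 1, with 5.85 in untreated replicate 2 and with 8.01 and 49.0 in the JQ1 lists. VCaP cells carry a fusion of TMPRSS2 with ERG, so that this gene lies in a rearranged locus. No test was run on these single regions.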
